A study of Drosophila melanogaster with 7 samples.

How the data were processed

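Expression was measured in adult head RNA of 7 libraries of Drosophila melanogaster, 3 from flies on a light-dark cycle (LD, replicates 2, 3 and 4) and 4 from flies in constant light (LL, replicates 1 to 4). Per the labels' protocols, ribosomal RNA was depleted from the purified RNA, stranded libraries were made and read as paired ends. The titles call the assay TRAP-seq, and the tagged cell type and the time of day of collection are not given in the sources used here. The labels do not say that the libraries came from separate groups of flies, so p-values measure the spread between these libraries. The labels name no LD replicate 1.

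The authors deposited length-scaled abundances (TPM) per transcript and library in a table of 30339 transcripts, with each transcript's length in bp, and the same rows in a second sheet in another order. Per the submitters' processing notes, fastp, STAR and DESeq2 were used with the genome build dm6. Their versions, settings and annotation are not given in the sources used here. The deposited p-values and adjusted p-values are the authors' own, once with all libraries and once without LD replicate 3, and were only counted and compared, never recomputed. A deposited log2 fold column held division errors in part of its values and was not used.

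TPM times transcript length was a whole multiple of 1 step in each library for 100% of values above 0 (within 0.001 of a read), so the reads behind each TPM value could be recovered. Isoforms of a gene appear to share reads, which was not tested, so sums over transcripts (2844756 in LD replicate 3 to 23382331 in LL replicate 2) were not taken as the reads of a library. Each gene was therefore represented by its transcript with the most recovered reads, which left 911071 to 7425747 reads per library. With this depth, the median tested gene had 28 reads in LD replicate 3 and 205 in LL replicate 2, and 1752 of the tested genes had 0 reads in LD replicate 3. Where a group had 0 reads in all its libraries, a floor of 3 reads per library, averaged over the group, gives the bound on the fold. It covers counting error only, since reads without molecular identifiers are not independent molecules.

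Of the transcripts, 231 named no gene and were left out (0.789% to 1.02% of TPM per library). The other 30108 belonged to 13796 genes, of which 13745 matched the given symbol table and have coordinates in Ensembl release 115 (BDGP6.54, the dm6 assembly). Coordinates are gene spans, 1-based. The table held 0 rows of the mitochondrial genome, rRNA or small RNAs. The reads of 362 genes equalled those of another gene in all libraries (genes with at least 50 reads in total), and these cannot be told apart. Near-identical copies such as Hsp70 and histone genes are uncertain too, since how the authors' counting treated multiply mapped reads is not given in the sources used here.

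Genes with a TPM of at least 1 in at least 3 libraries (8945) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean trend, two-sided, no covariates). The threshold was a Benjamini-Hochberg adjusted p of 0.05. Fold changes are differences of group means on the log2(TPM + 1) scale, where the added 1 shrinks the change of low genes. A library at or near 0 reads can instead move a fold away from the ratio of mean TPM, or turn its sign. AttA, named after its values were seen, was at 0.179 TPM in LD replicate 2. Its means were 143 TPM in LD and 35.5 TPM in LL, yet its log2 fold change was 0.49. The median residual SD was 0.67 on that scale. No table of read counts was used here, so the test planned for counts was not run.

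Of 36 gene lists fixed before the data were examined, 34 had at least 5 tested members (639 of 658 individually named members matched a row, the rest of the lists were name patterns), and the lists of mitochondrial-genome genes and small nucleolar RNAs had 0. They were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, all in limma, with Benjamini-Hochberg adjustment over the 34 lists. Counts adjusted over the list alone use the adjustment over its members only. Genes named in the text follow a rule set at the same time. It takes the 10 largest rises and falls past the threshold with a mean of at least 5 TPM in the higher group and no overlap between groups and, where fewer than 10 genes pass, the 10 smallest p per direction named as not passing. It adds up to 4 members with the smallest p per list and a fixed set (Tl, spz, drpr, ninaE, per, tim, repo, elav). Names that are only a CG, CR or lncRNA number were passed over unless among the first 3. Exceptions are named where they occur.

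The titles give LD and LL libraries the same numbers 2, 3 and 4. Deviations from the group means correlated at r = 0.124, 0.148 and 0.119 within these pairs, all above 0.1, so the numbers were treated as a possible pairing. The unmatched pair of LD replicate 2 and LL replicate 1 reached 0.140, and the other unmatched pairs lay below 0.1. This pairing comes from the data and the shared numbers, since the labels do not say what a number stands for. Depth fell in the same order of numbers, 2, 4 and 3, in both groups. LD held 5488798, 2684798 and 911071 reads in that order, and LL 7425747, 4508268 and 2905218. The correlations therefore cannot tell a pairing from a likeness in depth. A fit with the replicate number as a block was run beside the main one, in which LL replicate 1 has no partner.

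The scripts were tested on simulated data, 5 data sets with negative binomial reads for the 8945 genes at the real depths, 200 of them changed in each. The spread of each gene followed the smoothed trend of the real libraries with its mean, without differences between genes of like mean. For LL against LD the test called 6.40% of genes changed 2-fold, 50.6% of those changed 4-fold, 72.2% of those changed 8-fold and 80.7% of those changed 16-fold, and 0.062% of unchanged genes. Camera called 5 of 5 simulated lists of 25 genes raised 2-fold and 0 of 200 unchanged lists of independent genes.

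Alternatives covered the pseudocount, the filter on low values, rescaling, the prior variance, library weights, the block, leaving out each library, and the choice of transcript. Chosen after seeing the data were limma's voom on the recovered reads, fits that count identical genes once or sum histone copies, and the other ways to represent a gene. Other programs were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.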

Results

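RNA of adult fly heads was profiled in 7 sequencing libraries, 3 from female flies kept on a cycle of 12 h light and 12 h dark (LD, replicates 2, 3 and 4) and 4 from females kept for 3 days in constant white LED light of about 10000 lux (LL, replicates 1, 2, 3 and 4). The flies were 5 to 12 days old and were held at 25 °C. The titles name the assay as TRAP-seq, in which RNA bound to tagged ribosomes of chosen cells is sequenced. The labels do not say which cells carried the tag, and their extraction text describes total RNA. No unpurified input library was analysed here, so the values describe the sequenced RNA and not its enrichment over the whole head.

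Depth differed between the libraries. Counting 1 transcript per gene, the LD libraries held 5488798, 911071 and 2684798 reads (replicates 2, 3 and 4) and the LL libraries 4111196, 7425747, 2905218 and 4508268 reads (replicates 1 to 4). The least deep library, LD replicate 3, had reads on 7493 genes and the deepest, LL replicate 2, on 9879. The mean correlation of LD replicate 3 with the other libraries was r = 0.711 across genes, and that of each of the other 6 was 0.787 or higher. Genes are not independent replicates, so these correlations describe the libraries only.

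**Figure D1:**
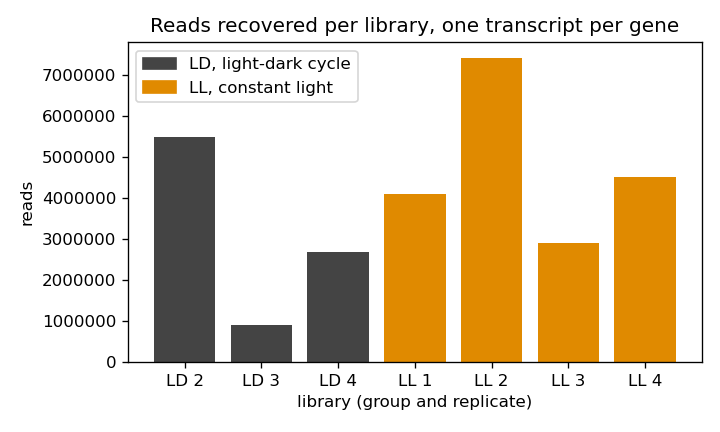
Reads recovered per library (y axis, 1 transcript per gene) for the 3 LD libraries (dark bars) and the 4 LL libraries (orange bars). LD replicate 3 held 911071 reads, fewer than each of the other libraries.

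The study's title names chronic light, the receptor Toll-1 and engulfment by glia, and the comparison of LL with LD asks which transcripts of the head differ after 3 days of constant light. In LL, 6 genes were higher and 0 were lower. Among them were the small heat shock genes Hsp22 and Hsp26. Hsp22, a mitochondrial chaperone (FBgn0001223, chromosome 3L, 9372931 to 9374964, plus strand, dm6), was at 5.71 ± 5.16 TPM in LD and 319 ± 64.1 TPM in LL (mean ± SD, here and below over 3 LD and 4 LL libraries), a log2 fold change of 6.14 with a standard error of 0.70 (limma adjusted p = 0.0115). Its neighbour Hsp26 (FBgn0001225, chromosome 3L, 9376418 to 9377427, minus strand), a cytosolic chaperone, was at 9.57 ± 4.41 TPM in LD and 133 ± 18.8 TPM in LL, a log2 fold change of 3.76 with a standard error of 0.35 (limma adjusted p = 0.00834). Ldh, lactate dehydrogenase (FBgn0001258, chromosome 3L, 6259105 to 6262694, minus strand), was at 5.82 ± 2.05 TPM in LD and 102 ± 41.0 TPM in LL, a log2 fold change of 3.87 with a standard error of 0.39 (limma adjusted p = 0.00878).

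Hsp70Bbb and Hsp70Bc, copies of the main heat-inducible chaperone Hsp70, rose as well. Hsp70Bbb (chromosome 3R, 12502510 to 12504856) had a log2 fold change of 2.98 with a standard error of 0.33, from 15.1 ± 8.56 to 117 ± 7.04 TPM (limma adjusted p = 0.0115). Hsp70Bc (chromosome 3R, 12509076 to 12511461) had a log2 fold change of 2.72 with a standard error of 0.33, from 17.5 ± 9.75 to 111 ± 7.24 TPM (limma adjusted p = 0.0181). The Hsp70 copies are near-identical in sequence, so their separate values are uncertain. Hsp70Aa and Hsp70Ab, named after their values were seen, did not pass (limma adjusted p = 0.534 and 0.533). LD replicate 2 held them at 229 and 231 TPM, within the range of the LL libraries. CG4456, the sixth gene, had exactly the reads of Hsp22 in all libraries. The transcripts used for both have the same length (1900 bp), and the gene spans overlap. The 6 genes therefore stand for 5 read counts. In LD replicate 3 Hsp22 had 0 reads, and without that library its log2 fold change was 5.06. Each of the 6 genes was higher in all 4 LL libraries than in any LD library.

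The test covered 8945 genes, of which 712 had an unadjusted p under 0.05, 495 higher and 217 lower in LL. The groups did not overlap for 742 genes (8.30% of those tested, where chance gives 5.71%). In the paired fit (replicate number as a block) the log2 fold changes were 6.26 for Hsp22, 4.00 for Ldh and 3.72 for Hsp26 (limma adjusted p = 0.0745 for each), and 3.00 for Hsp70Bbb and 2.72 for Hsp70Bc (limma adjusted p = 0.115 and 0.141). These lay near the log2 fold changes of the main fit (6.14 for Hsp22, 3.87 for Ldh and 3.76 for Hsp26). The replicate terms leave fewer degrees of freedom, and whether this alone cost the calls was not tested. The block did not lower the count in every fit. With voom on the recovered reads and the same block, more genes passed than in the main fit (count given under the processing). The count past the threshold was 0 in the paired fit, 0 without LL replicate 2 and 0 without LL replicate 4. It was 2 without LL replicate 1, 3 without LL replicate 3, 15 without LD replicate 2 and 39 without LD replicate 4.

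The wider list of heat shock proteins and chaperones was higher in LL, with a positive log2 fold change for 23 of its 25 tested members and a median of 1.11. Of these members 5 rose in the test over all genes and 16 when adjusted over the list alone. The 5 include Hsp22 and CG4456, which have the same reads, and the near-identical copies Hsp70Bbb and Hsp70Bc. With genes of identical reads counted once, the median of the list was 1.02 (camera adjusted p = 5.63e-12 at the preset correlation). The list passed camera's test with the preset correlation (adjusted p = 1.89e-13). It did not pass with an estimated correlation (adjusted p = 0.309 with an estimated correlation). Among members that did not pass over all genes, Hsp70Ba had a log2 fold change of 2.18 with a standard error of 0.35 (limma adjusted p = 0.115) and Hsp70Bb of 1.38 with a standard error of 0.23 (limma adjusted p = 0.120). Hsp23, another small heat shock protein, named after its values were seen, had one of 1.95 (limma adjusted p = 0.120).

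**Figure D2:**
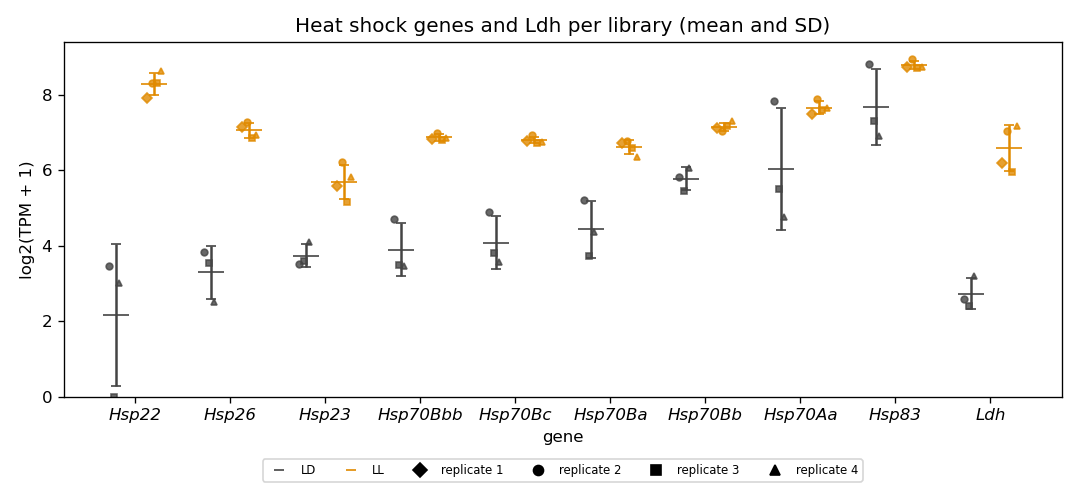
Expression of 9 heat shock genes and Ldh (x axis) as log2(TPM + 1) (y axis) in the 3 LD (dark) and 4 LL (orange) libraries. Points are libraries, with a shape for each replicate number, and bars are the mean and SD of the log values. For Hsp22, Hsp26, Hsp70Bbb, Hsp70Bc and Ldh all 4 LL libraries lie above the LD libraries. For Hsp70Aa, named after its values were seen, LD replicate 2 (229 TPM) lies within the LL range.

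Of the 20 circadian clock genes tested, 13 had a positive and 7 a negative log2 fold change, and none passed the test over all genes. The transcription factor vri (chromosome 2L, 5288944 to 5311223) was at 13.7 ± 8.86 TPM in LD and 77.6 ± 7.48 TPM in LL, a log2 fold change of 2.64 with a standard error of 0.45 (limma adjusted p = 0.120). The feedback repressors tim and per were at 30.2 ± 11.0 and 30.8 ± 8.40 TPM in LD and at 96.0 ± 27.7 and 70.6 ± 8.52 TPM in LL. Their log2 fold changes were 1.67 for tim (standard error 0.34, limma adjusted p = 0.285) and 1.19 for per (standard error 0.27, limma adjusted p = 0.382). The deubiquitinase gene Usp8 had a log2 fold change of 2.52 with a standard error of 0.56 (limma adjusted p = 0.382). Adjusted over the list alone, these 4 of the 20 members passed and 0 passed with a lower value. All 4 LL libraries lay above the LD libraries for each of them. Other members had lower values, among them Clk (log2 fold change -0.82, standard error 0.56) and the blue-light receptor gene cry (-0.48, standard error 0.25), both named after their values were seen.

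As a set, the clock list had a median log2 fold change of 0.18 and did not pass camera (adjusted p = 0.178). Fry, which asks whether the genes move on balance in 1 direction, gave an adjusted p of 0.0109. For the heat shock list fry also gave an adjusted p of 0.0109. The histone, antimicrobial, oxidative stress and proteasome lists passed camera at the preset correlation but did not pass fry (fry adjusted p = 0.261, 0.778, 0.117 and 0.332). The labels give no time of day for the collection of either group.

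**Figure D3:**
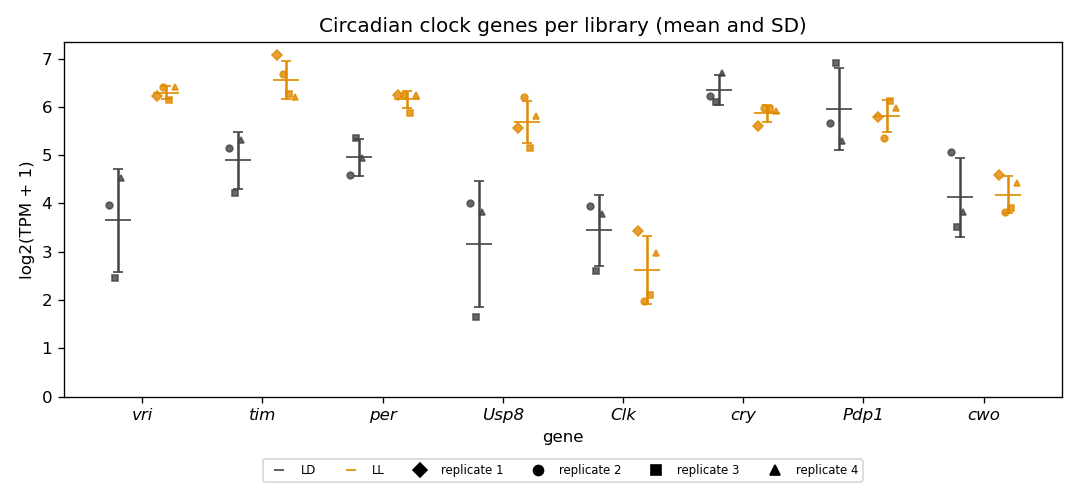
Expression of 8 clock genes (x axis) as log2(TPM + 1) (y axis) in the 3 LD (dark) and 4 LL (orange) libraries. Points are libraries, with a shape for each replicate number, and bars are the mean and SD of the log values. The LL libraries lie above all LD libraries for vri, tim, per and Usp8.

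Genes for oxidative stress and detoxification and for the proteasome were slightly higher in LL as sets. In the first list 28 of 32 members had a positive log2 fold change (median 0.44, camera adjusted p = 0.00423, and adjusted p = 0.624 with an estimated correlation). Its members with the smallest p were GstD10, a glutathione transferase, with a log2 fold change of 1.86, and Trxr1, thioredoxin reductase, with 0.72. GstD10 rests on few reads (3, 1 and 0 in LD replicates 2, 3 and 4, and 10 to 45 in the LL libraries). In the proteasome list 32 of 34 members were positive (median 0.31, camera adjusted p = 0.00989, and adjusted p = 0.820 with an estimated correlation), among them Prosbeta5 with 0.85 and Rpt1 with 0.81. No member of either list passed on its own, over all genes or over the list alone. Without LD replicate 2 neither list passed (camera adjusted p = 0.109 and 0.497), though the medians were 0.53 and 0.28. The unfolded protein response list had a median of 0.17 (camera adjusted p = 0.435), and 1 of its 27 members, the ER chaperone Cnx99A, passed over the list alone (log2 fold change 1.29, limma adjusted p = 0.382 over all genes).

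Antimicrobial peptides, the secreted effectors of fly immunity, had lower values in LL. Of 33 tested members 22 had a negative log2 fold change, with a median of -0.43 (camera adjusted p = 0.00200, and adjusted p = 0.850 with an estimated correlation). CecB, a cecropin (chromosome 3R, 30213315 to 30213797), was the 1 member that passed over the list alone. It averaged 17.6 TPM in LD (6.64, 26.3 and 19.9 TPM in replicates 2, 3 and 4) and had 0 reads in all 4 LL libraries, which against a floor of 3 reads per library makes it at least 14.4-fold lower. It did not pass over all genes (limma adjusted p = 0.0746), and its LD libraries held 20, 13 and 32 reads. Drsl4, a drosomycin-like peptide, was at 81.5 ± 50.3 TPM in LD and 18.9 ± 12.8 TPM in LL (limma adjusted p = 0.430). Without LD replicate 4 the list did not pass (camera adjusted p = 0.853) and its median was 0.21, and without LD replicate 2 the median was -0.90.

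The genes of the study's title did not pass the test. In simulated data that test called 6.40% of genes changed 2-fold and 50.6% of those changed 4-fold, so a missed change cannot be excluded. The tagged cells are not named, so levels in glia cannot be read from these values. Tl, which encodes Toll-1 (chromosome 3R, 26799041 to 26842403), was at 14.7 ± 9.98 TPM in LD and 9.22 ± 2.26 TPM in LL, a log2 fold change of -0.43 with a standard error of 0.51 (limma adjusted p = 0.856). Its ligand gene spz had a log2 fold change of 0.43 with a standard error of 0.46, and the glial engulfment receptor drpr one of -0.10 with a standard error of 0.26. No member passed, over all genes or over the list alone, among 9 Toll receptors and spz ligands (median -0.20, camera adjusted p = 0.606), 26 Toll pathway genes (median -0.15, adjusted p = 0.396), 23 Imd pathway genes (median -0.14, adjusted p = 0.346) or 37 engulfment genes (median -0.01, adjusted p = 0.606). The same held for 9 genes of phosphatidylserine exposure (median 0.03, adjusted p = 0.899) and 12 JAK-STAT and Turandot genes (median 0.08, adjusted p = 0.606). The Imd transcription factor gene Rel had the smallest p of its list, at 59.9 ± 11.9 TPM in LD and 29.3 ± 5.57 TPM in LL (limma adjusted p = 0.430).

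Histone transcripts were lower in LL as a set. A negative log2 fold change was found for 113 histone genes and a positive one for 2, with a median of -0.63 (camera adjusted p = 8.32e-25, and adjusted p = 0.624 with an estimated correlation). None passed over all genes and 23 passed over the list alone. Without LD replicate 3 the median was -0.38. Most of these genes are near-identical repeated copies, so they are not separate measurements. Summed over copies, the 23 His2B genes were at 5146 ± 2530 TPM in LD and 1856 ± 329 TPM in LL, a log2 fold change of -1.34 with a standard error of 0.38, and the 23 His3 genes had one of -0.28 with a standard error of 0.55 (limma adjusted p = 0.476 and 0.926). With copies summed per kind the list did not pass (camera adjusted p = 0.0783).

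Genes of the eye and nervous system gave no list past the threshold. ninaE, the main rhodopsin of outer photoreceptors, was at 7087 ± 2264 TPM in LD and 10163 ± 2849 TPM in LL (log2 fold change 0.53, standard error 0.33). The phototransduction list had a median of 0.10 over 30 genes (camera adjusted p = 0.527). Within it Rh5, a blue-sensitive rhodopsin, was at 165 ± 56.9 TPM in LD and 81.5 ± 14.2 TPM in LL, and the calcium-binding protein gene Cpn had a log2 fold change of 0.75 (limma adjusted p = 0.430 and 0.487). Medians and camera adjusted p were -0.19 and 0.710 for photoreceptor structure, 0.32 and 0.606 for histamine transmission, and 0.04 and 0.899 for the active zone. They were 0.10 and 0.899 for pan-neuronal genes, 0.05 and 0.740 for glial genes, and 0.13 and 0.899 for olfactory genes. The glial transcription factor repo had a log2 fold change of -0.73 (standard error 0.37) and the neuronal RNA-binding protein elav 0.36 (standard error 0.42), and neither passed. In the pigment and lens list (median 0.14, camera adjusted p = 0.838) the eye pigment transporter w passed over the list alone, at 83.9 ± 36.7 TPM in LD and 23.5 ± 8.85 TPM in LL (limma adjusted p = 0.414 over all genes).

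Lists for other tissues of the head, feeding and hormones did not pass in the main test, and 3 of them passed in the paired fit. Fat body genes had a median of -0.38 and a mean of 0.15 (camera adjusted p = 0.416). Within that list the yolk protein gene Yp2 was at 3536 ± 407 TPM in LD and 1813 ± 662 TPM in LL, and the glucosidase gene tobi at 4.81 ± 4.90 and 33.4 ± 19.8 TPM (limma adjusted p = 0.430 for each). Hemocyte genes had a median of -0.30 (adjusted p = 0.433) and muscle genes one of -0.29 (adjusted p = 0.0836, and 0.0167 in the paired fit). The muscle list passed in 5 of 26 alternatives, with medians from -0.52 to 0.11 (camera adjusted p = 0.850 with an estimated correlation). The insulin and feeding list had a median of -0.25 (adjusted p = 0.110, 0.0242 in the paired fit and 0.850 with an estimated correlation) and passed in 8 of 26 alternatives. The juvenile hormone and ecdysone list had one of -0.41 (adjusted p = 0.0546, 0.0328 in the paired fit and 0.820 with an estimated correlation) and passed in 14 of 26 alternatives. Cuticle protein genes had a median of 0.65 (adjusted p = 0.0781). In that list Acp65Aa had 0 reads in all LD libraries and 12.7 ± 6.69 TPM in LL, at least 6.18-fold higher against a floor of 3 reads per library, and passed over the list alone (limma adjusted p = 0.0804 over all genes).

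Of the remaining lists, medians and camera adjusted p were 0.19 and 0.110 for cytosolic ribosomal proteins, 0.15 and 0.409 for nuclear genes of oxidative phosphorylation, and -0.10 and 0.416 for cytochrome P450 genes. They were -0.03 and 0.740 for JNK and MAPK signaling, 0.10 and 0.753 for cell death, -0.02 and 0.826 for autophagy and lysosome, and 0.42 and 0.346 for activity-regulated genes. In the last, CG14186 passed over the list alone, at 45.5 ± 5.14 TPM in LD and 92.0 ± 16.7 TPM in LL (limma adjusted p = 0.430 over all genes). In total 5 of 34 lists passed camera with the preset correlation, 3 higher and 2 lower in LL, and 0 with an estimated correlation. In the paired fit 8 passed, without LD replicate 3 also 8, and without LL replicate 1 it was 11.

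**Figure D4:**
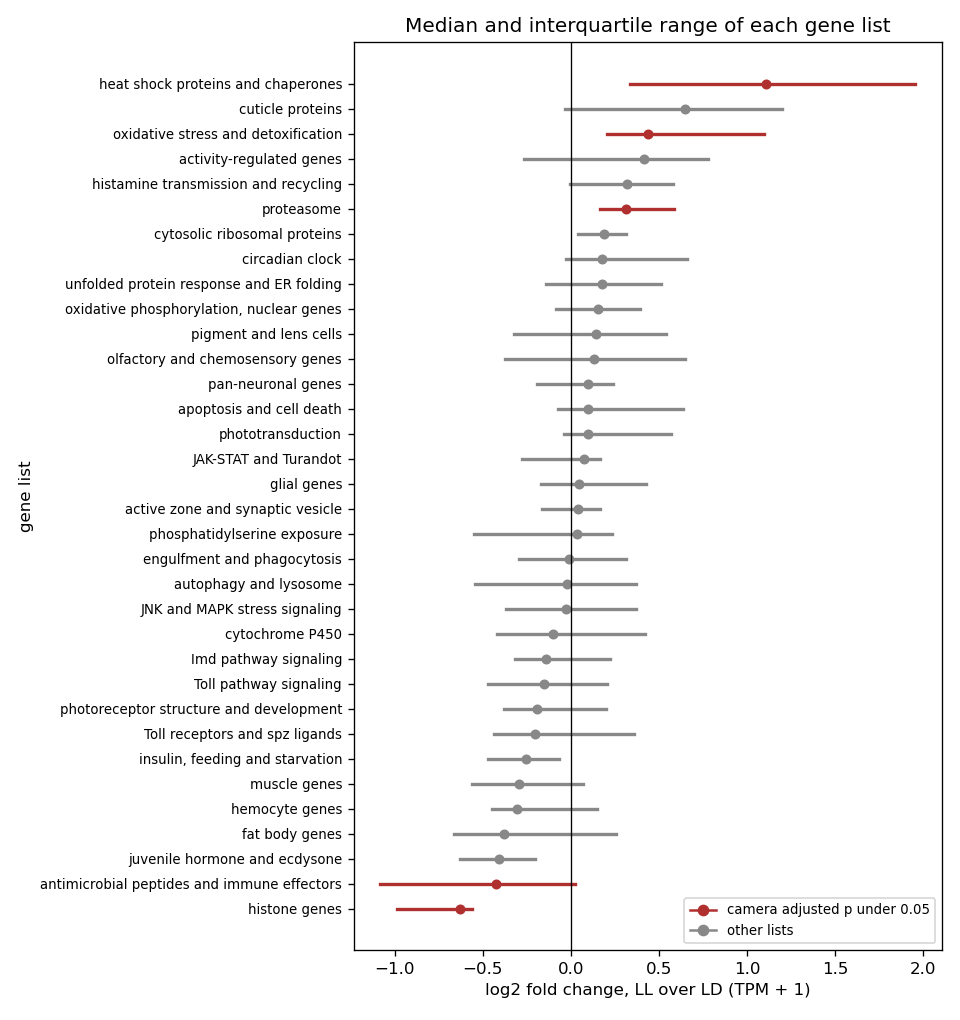
Median (point) and interquartile range (line) of the log2 fold change of LL over LD (x axis, on TPM + 1) for each of the 34 gene lists (y axis). Red marks the 5 lists with a camera adjusted p under 0.05 at the preset correlation. The heat shock list has the highest median (1.11) and the histone list the lowest (-0.63).

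No gene was lower in LL past the threshold of this test. The chromatin protein gene HmgZ had one of the smallest p in that direction, at 126 ± 18.9 TPM in LD and 62.0 ± 7.83 TPM in LL (log2 fold change -1.01, standard error 0.23, limma adjusted p = 0.382). Npc2h, of a family of sterol-binding proteins, was at 81.2 ± 36.6 TPM in LD and 29.3 ± 7.82 TPM in LL, and phu at 25.2 ± 11.4 and 6.06 ± 1.75 TPM (limma adjusted p = 0.430 for each). CG33127, Polr1D, Nop10 and tej had at most 203, 24, 12 and 74 reads in an LD library and at most 4, 3, 3 and 43 in an LL library, and did not pass (limma adjusted p = 0.120, 0.141, 0.251 and 0.430). On the rising side Rdh was listed at 0 in the LD libraries and at 8.16 ± 3.36 TPM in LL, at least 2.84-fold higher against the same floor (limma adjusted p = 0.120).

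The authors' deposited table holds adjusted p-values of their own test, once with and once without LD replicate 3. A gene was counted when any of its transcripts passed, and its smallest adjusted p is given. With LD replicate 3, the authors' deposited table put 17 genes under an adjusted p of 0.05, of which 12 were higher and 5 lower in LL. Without it the authors' deposited table put 18 there, 14 higher and 4 lower, and 9 genes were in both sets. The limma test shared 3 genes with the first set and 6 with the second. The 3 not in the first set (Hsp22, CG4456 and Ldh) had no adjusted p there in the authors' deposited table. In the authors' deposited table with LD replicate 3, Hsp26 (adjusted p = 7.53e-13), Hsp70Bbb (5.37e-09), vri (5.19e-05), tim (0.00692) and w (0.00692) were among the genes passing. In the authors' deposited table without it, Hsp22 (adjusted p = 1.48e-25), Ldh (1.10e-08), Usp8 (0.000590) and per (0.00871) passed. For the transcripts used here, the authors' adjusted p without LD replicate 3 was 0.00925 for Usp8 and 0.0351 for per. With that library it was 0.000179 for vri and 0.00931 for tim.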

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

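The search for a library far from its group and the counts of genes and lists over other splits were planned, and the other tests in this part were chosen only after the result was seen. In LL, 13 of 155 values tested had 1 library far from the other 3, its gap to the nearest of them filling most of the range of the group. Chance gives such a library in about 1 in 20 groups. The 3 LD libraries were not tested, since groups of 3 are too small.

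In LL replicate 1, repo was at 14.1 TPM against 8.77 to 9.60 in the others (gap over range 0.8465), GstD10 at 2.14 against 4.99 to 5.37 (0.8796) and Trxr1 at 156 against 189 to 193 (0.9104). In LL replicate 2, Act5C was at 829 TPM against 636 to 669 (0.8301), eys at 125 against 74.9 to 76.4 (0.9709), tej at 2.21 against 0 to 0.243 (0.8898) and Nop10 at 0.945 against 0 (1). In LL replicate 3, per was at 57.8 TPM against 74.5 to 75.1 (0.9608), Dronc at 5.43 against 3.26 to 3.41 (0.9325) and Prosbeta1 at 72.6 against 38.4 to 43.2 (0.8588). In LL replicate 4, drpr was at 31.3 TPM against 40.9 to 41.5 (0.9389), CG33127 at 0.635 against 0 (1) and Polr1D at 1.17 against 0 (1). Nop10, CG33127 and Polr1D rest on at most 4 reads in that library.

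The 7 libraries can be split into 3 and 4 in 35 ways. The real split gave 6 genes, 1 of the 35 gave as many (the real one) and the highest of the others gave 0. That share (0.0286) is the smallest that 35 splits can give and does not exclude chance. It also holds only if the libraries are exchangeable across replicate numbers. At an unadjusted p under 0.05 the real split gave 712 genes, and 3 of the 35 splits gave as many, with 794 the highest of the others. For gene lists the real split gave 5, and 17 of the 35 gave as many, with 12 the highest of the others, so chance cannot be excluded for the number of lists. That split set LL replicates 2, 3 and 4 against the rest. As small a camera p as the real one was given by 3 of the 35 splits for histone genes, 2 for oxidative stress and detoxification and 7 for the proteasome. Among the 8 splits that part all 3 pairs of like number, which are too few for a share under 0.05, the highest others were 0 genes and 12 lists, and the remaining splits keep at least 1 pair in the same group. With the replicate block the real split gave 0 genes in the fit on log2(TPM + 1).

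The heat shock genes were higher in LL. The low depth of LD replicate 3 is argued against as the whole cause by a median log2 fold change of 0.92 for the list without that library (1.11 with it). Reads shared between near-identical copies are argued against by a median of 0.62 over the 17 members outside the Hsp70 copies, Hsp22 and CG4456, 15 of them positive (camera p = 6.43e-06 in limma, p = 0.00623 with an estimated correlation, and exact p = 0.0286 over the 35 splits, the smallest they can give), and a shift of the whole TPM scale by a median of 1.09 under the rescaling that lowered it most. The p-values of the 17 members are not adjusted over lists. For the whole list camera with an estimated correlation gave p = 0.00910 unadjusted and 0.309 adjusted. Among the 35 splits only the real one gave the list so small a camera p, the smallest other being 6.19e-09. The 35 splits ignore the possible pairing by number, and the 8 that part all 3 pairs are too few for a share under 0.05. A response to constant light remains open as an untested biological explanation, as do differences in handling or collection time that go with the groups.

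The antimicrobial peptide list had a negative median in LL against LD, with 22 of 33 members negative, and did not pass with an estimated correlation (limma camera adjusted p = 0.850). High levels in LD replicate 4 alone are a candidate explanation, since without that library the median log2 fold change of the list was 0.21 (-0.43 with it), and 13 of the 35 splits gave the list as small a camera p as the real one. A lower share of fat body RNA in LL cannot be told apart from other explanations, because the 7 most abundant fat body genes (Yp1, Yp2, Yp3, Lsp2, apolpp, Lsd-2 and Tsf1) had a median of -0.36 but ranged from -1.02 to 2.07. All 7 had reads in these head libraries. An effect of light on these peptides was not tested apart from these.

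The clock genes vri, tim, per and Usp8 had higher values in LL. Low depth of LD replicate 3 is argued against as the whole cause by their median log2 fold change of 1.58 without that library (2.09 with it). Collection at another phase of the clock cannot be told apart from an effect of constant light. Clk and cry, which peak opposite to per and tim in a cycle, had log2 fold changes of -0.82 (standard error 0.56) and -0.48 (standard error 0.25), a mean of -0.65, each within 2 standard errors of 0, and no collection time is given. The 4 genes were grouped for their values, although per and tim were also in the fixed set, so their level is a hypothesis.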

How the results depend on the processing

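Fits with voom, other transcripts per gene, identical genes counted once and histone copies summed were chosen after seeing the data, and the others before. Of 3472 values of single genes under an alternative, 3402 stayed on their side of the threshold, 3399 of them with the same sign, as did 818 of 883 medians of single lists, 754 of them with the same sign. Most named genes did not pass in the main test, so these counts say little of the 6 genes that did. Of 24 alternatives, Hsp22 passed in 14, Ldh, Hsp26 and Hsp70Bbb in 18 each and Hsp70Bc in 16. CG4456 passed in 14 of 23. The median of the antimicrobial list, which passed in the main test, turned from -0.43 to 0.21 without LD replicate 4, where it did not pass, and lay between -0.90 and 0.21 when 1 library was left out. The cause was not tested for any of these changes or those below. The count of 6 genes became 0 with the replicate block, 2 with voom and quality weights and 41 with voom and the block, and lay between 0 and 39 when 1 library was left out (0 without LL replicate 2 or 4, 39 without LD replicate 4). The other alternatives gave 4 to 9 genes. Of 6 genes 2 were shared with the main test without a trend in the prior variance and 4 with voom, in both with 5 higher and 1 lower. Voom lost Ldh and Hsp26 and added vri and, lower in LL, CG12116 (log2 fold change -2.06, named after its values were seen). Over its 24 alternatives vri passed in 4 (adjusted p 0.00246 to 0.549). Quantile normalization gave 6 higher and 1 lower gene and 5 higher and 2 lower lists, where the main test gave 6 and 0 genes and 3 and 2 lists. The count of 5 lists became 0 with an estimated correlation, 8 with array weights, 8 with the block, 8 with voom, 9 with voom and quality weights, 16 with voom and the block and 10 with voom without LD replicate 3, and lay between 4 and 11 when 1 library was left out. The block kept all 5 lists and added those for muscle, insulin and feeding, and juvenile hormone and ecdysone, and changed no other call among named genes and lists. The log2 fold change ranged from 5.04 to 7.34 for Hsp22 (adjusted p 5.70e-05 to 0.311), 3.24 to 4.42 for Ldh (0.00246 to 0.307), 3.29 to 4.03 for Hsp26 (0.000975 to 0.148), 2.67 to 3.39 for Hsp70Bbb (0.00119 to 0.115) and 2.45 to 3.12 for Hsp70Bc (0.00209 to 0.141). The heat shock list passed in 25 of 26 alternatives, the exception being the estimated correlation. Of the lists that did not pass in the main test, juvenile hormone and ecdysone passed in 14 of 26 (median -0.60 to -0.14, adjusted p 0.00168 to 0.820). The authors' deposited counts were 17, also with a fold over 2, and 18 without LD replicate 3. Rescaling without mitochondrial, ribosomal and small RNAs was not run, as the table has 0 such transcripts. The test planned for a table of counts was not run, as none was used here, and voom was fitted to the recovered reads. Depth limits genes of few reads, with 1752 tested genes at 0 reads in LD replicate 3.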

Other observations

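The test on the CCT genes below was chosen only after the result was seen. The prediction for the glycolytic genes was written before that set was tested. The glycolytic genes are not among the 36 lists fixed in advance, and their test takes up the higher level of Ldh. The single genes named in this part were chosen after their values were seen. CCT8, a subunit of the cytosolic CCT chaperonin that folds actin and tubulin, was at 19.7 ± 8.97 TPM in LD (mean ± SD, 3 libraries) and between 51.8 and 64.1 TPM in the 4 LL libraries, all above LD (limma adjusted p = 0.382). A hypothesis was that all subunits of the chaperonin are higher. The other 7 CCT genes had positive log2 fold changes with a median of 0.91, among them CCT5 at 40.3 ± 16.1 and 90.4 ± 18.1 TPM, and limma camera over them gave p = 3.04e-05 (p = 0.0154 with an estimated correlation, and exact p = 0.0286 over the 35 splits of the libraries, the smallest they can give). These p-values are not adjusted over the gene lists. The 35 splits ignore the possible pairing by number, and the 8 that part all 3 pairs are too few for a share under 0.05. LD replicate 3 was the lowest LD library for CCT3 (2 reads), CCT4, CCT5, CCT6, CCT7 and CCT8 (21 reads). It was the highest for CCT1 and CCT2. The set was not tested without that library. The chaperonin genes may be higher as a set in LL, but none passed on its own over all genes.

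Ldh was higher in LL, and a hypothesis was that the glycolytic enzyme genes are higher with it. Of 10 such genes, 6 had a positive log2 fold change, with a median of 0.08. Limma camera, fitted across all genes, gave p = 0.745 for the set (exact p = 0.743 over the 35 splits), which argues against a rise of the set as a whole. Pfk, the phosphofructokinase gene, had a log2 fold change of -0.74 (standard error 0.27) and Pgk one of -0.44 (standard error 0.23), with all 4 LL libraries below the LD libraries for both. Pgi had one of 0.55 (standard error 0.27) and Gapdh2 one of 0.45 (standard error 0.25), and none of these 4 passed over all genes.

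Single LD libraries stood apart in different genes. LD replicate 2 held Hsp70Aa at 229 TPM and Hsp70Ab at 231 TPM, where LD replicates 3 and 4 held Hsp70Aa at 44.8 and 25.9 and Hsp70Ab at 44.9 and 26.0, and the LL libraries 179 to 237 for Hsp70Aa. The same library had daw at 132 TPM and AkhR at 83.3 TPM, above the other 6. LD replicate 3 had the muscle genes Mf at 370 TPM and TpnC41C at 73.2 TPM. LD replicate 4 had the antimicrobial peptide genes DptA at 1108 TPM, DptB at 1071 TPM, Dro at 1232 TPM and AttA at 392 TPM, where LD replicates 2 and 3 had DptA at 99.3 and 252 TPM. The LL libraries ranged less, with AttA at 35.5 ± 0.521 TPM.

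Of the transcripts that name no gene, 122 passed the filter on low values, and 0 passed the limma test, with 3 at an unadjusted p under 0.05.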
